A study of Mus musculus with 6 samples.

How the data were processed

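Total RNA from whole kidneys of 6 samples was labelled with Cy3 and hybridised to 1-colour Agilent arrays, per the labels. The files are scanner output of Agilent Feature Extraction 10.7.1.1, per the file headers and the submitters' processing notes. The intensity values in the deposited scanner files are in linear units, and the processed signal was already background-subtracted and detrended, per the file headers. The deposited series matrix holds a linear ratio. Set against the scanner values, it equals each probe's mean processed signal divided by 1 factor per array, within rounding, so its scale and direction are settled. The column medians are 0.105, 0.104 and 0.103 for WT and 0.100, 0.098 and 0.099 for Pck1-CKO. The software of that scaling is not given in the sources used here.

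The log2 of the processed signal was taken, spots with a non-uniformity or population outlier flag were left out, spots of a probe were averaged, and each array's 75th percentile over non-control probes was subtracted. Flags removed between 46 and 94 spots per array, and 0 spots were saturated. Signals were scaled with a 75th percentile between 529.0 and 583.3. Probes were named through RefSeq accessions without versions, from a table of the GRCm38.p6 assembly. The files use another build, so no coordinates are given. Of 56605 probes, 34675 had 1 gene symbol, for 23785 symbols, and 21930 stayed unnamed. Probes well above background on at least 3 of 6 arrays were kept, 38370 in all and 25519 with a symbol. The brightest probe with a value on every array stood for a gene, which gave 17135 genes. Among genes past the threshold, 490 had other tested probes, and 543 of those 629 probes moved the same way.

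Genes were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, 2-sided, without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors of log2 changes are standard errors from this fit. Where a gene was not well above background on any array of a group, only a bound on its fold is given for the processed signal. It sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the gene's own signal. Medians of the lists with such genes at their bound were the same to 2 decimals. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, for lists of at least 5 tested genes. The 44 lists hold 1029 distinct genes, of which 1028 matched a gene symbol and 985 were tested.

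The groups, the tests of genes and lists, the lists and the rule for naming genes were fixed before the data were examined, as were the alternatives except 2, chosen after seeing the data. Genes named in the text were drawn from Pck1, the 10 genes with the largest change in each direction that passed the threshold, separated the groups and had a symbol other than a clone or predicted-gene name, and up to 3 members of each list that passed. In a list with no such member at most the 1 with the lowest p was named. Alternatives covered normalization, background correction, source of values, filter, choice of probe, variance model, array weights, flags, left-out arrays, a replicate block and the list test. Background correction with normexp (offset 50) had been planned on mean signals and used the median signals that the files hold. A block for slide or scan was not applicable, since all arrays shared slide 1 and scan 1.

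The procedure was tested on simulated data for the comparison of Pck1-CKO with WT, over 17135 genes with 3 arrays per group and 200 changed genes. It called 14% of genes changed by 0.25 on the log2 scale, 54% at 0.5, 88% at 1 and 90% at 2, and 2.38% of calls were false. The simulated noise was independent between genes and arrays, so these shares do not cover noise that genes share or that shifts a whole array. The numbers of the samples were not used as pairs.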

Results

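Gene expression was measured in whole mouse kidney on 6 Agilent arrays, 1 per sample. Of these, 3 were labelled wild-type (WT) and 3 Pck1-CKO, a knockout of Pck1 directed to the renal proximal tubule by a γGT-Cre transgene. The animals were C57BL/6J mice killed at 32 weeks, and the controls were littermates matched for age and sex. Pck1 encodes the cytosolic phosphoenolpyruvate carboxykinase, an enzyme of gluconeogenesis. Between 37118 probes (WT 1) and 38707 probes (WT 2) lay well above background on an array, of 56605 probes. The number of arrays limits the precision of every value. The labels do not say that each array came from a separate mouse, so p-values measure the spread between these samples.

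The targeted gene was examined first. Pck1 was bright on every array and was not lower in the arrays labelled Pck1-CKO. Its normalised log2 signal was 6.29, 6.32 and 5.63 in the WT arrays and 6.44, 6.60 and 6.90 in those labelled Pck1-CKO. The log2 change was 0.56 ± 0.22 (SE, n = 3 per group), with limma adjusted p = 0.152, so it did not pass the test. The array carries 1 Pck1 probe (A_66_P121110), and its position relative to the deleted part is not given in the sources used here. A probe outside that part checks nothing, so the signal neither bears out nor refutes the labels. All directions below are those of the arrays labelled Pck1-CKO relative to those labelled WT.

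The comparison of both genotypes asks what loss of proximal tubule Pck1 changes in the kidney of mice described as albuminuric. The largest increases included Ucp1, which uncouples respiration in brown fat and had a log2 change of 5.23 ± 0.85 (adjusted p = 0.0317), 37.5-fold. Cidea and Cox8b, also typical of brown fat, rose by 3.83 and 3.88 on the log2 scale. These sizes rested in part on WT 1, without which the log2 changes were 4.23 for Ucp1, 2.97 for Cidea and 3.12 for Cox8b. With normexp that of Ucp1 was 4.62. The largest decreases included the amino acid transporter gene Slc7a12 at -2.08 ± 0.25 (adjusted p = 0.02). Of 17135 genes tested with limma, 743 were higher and 634 lower at an adjusted p under 0.05. Most changes were small. Their median absolute log2 size was 0.39, and 80 of the higher and 47 of the lower genes changed by at least 2-fold. In each of the 1377 genes past the threshold all 3 arrays of one group lay above all 3 of the other. The groups did not overlap in 38.3% of all tested genes, where chance gives 10%. These counts depended on single arrays. They were 39 higher and 31 lower without WT 1, 22 and 13 without WT 2, 16 and 9 without Pck1-CKO 1, and 19 and 10 without Pck1-CKO 2. Of the 85 named genes past the threshold, 69 no longer passed without WT 1, 78 without WT 2, 20 without WT 3, 78 without Pck1-CKO 1, 78 without Pck1-CKO 2 and 21 without Pck1-CKO 3. All arrays were on slide 1 and in scan 1, with WT in slide row 1 and Pck1-CKO in slide row 2, so slide row and genotype cannot be told apart. The sample number was the slide column in both groups, and with it as a block 4 of the 1377 genes passed.

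**Figure D1:**
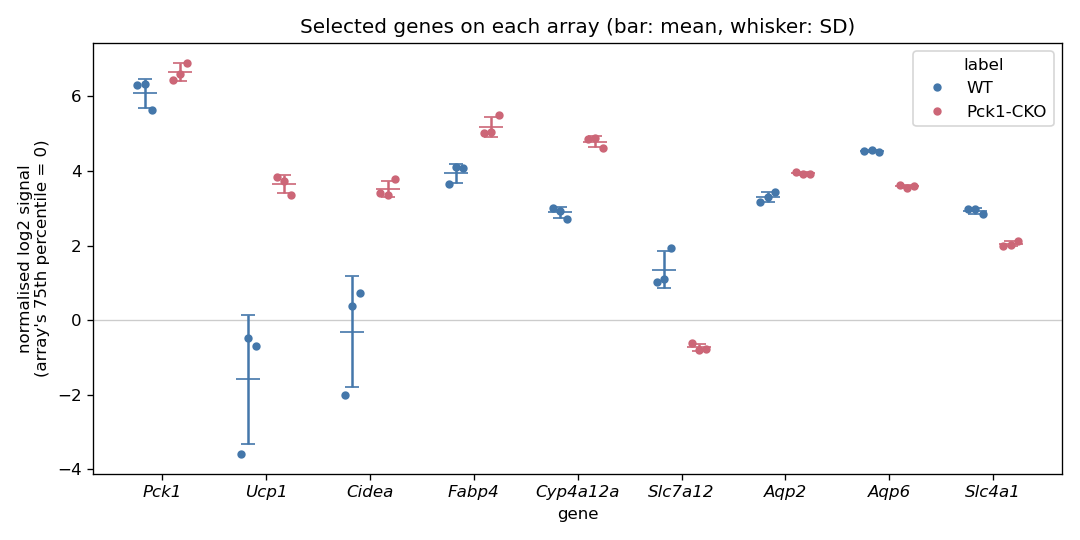
Normalised log2 signal (y axis, each array's 75th percentile at 0) of 9 genes (x axis) on the 3 WT and 3 Pck1-CKO arrays. Points are arrays, horizontal bars are means and whiskers SDs. Pck1 was not lower in the Pck1-CKO arrays, and Ucp1 was at -3.59 in WT 1 against -0.47 and -0.70 in the other WT arrays.

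The other genes with the largest increases were Elobl, Cyp2b10, Cyp2b9, Otop1, Hp, Lncbate10 and Ctxn3. Elobl, Cyp2b9 and Lncbate10 were not well above background on any WT array. They were at least 26.0-fold, 7.02-fold and 3.49-fold higher in Pck1-CKO, with limma adjusted p = 0.0336, 0.0359 and 0.00438. These bounds hold for the processed signal. After background correction with normexp, whose offset shrinks dim signals, the fitted log2 changes of Elobl, Cyp2b9 and Lncbate10, which are no bounds, were 2.48, 1.31 and 0.57. Cyp2b10, a cytochrome P450 gene, rose by 5.12 on the log2 scale and was well above background on 1 of 3 WT arrays. Cyp2b9 and Cyp2b10 are related genes. Signal shared between their probes was not examined and may leave each value uncertain. Otop1 rose by 4.27, Hp (haptoglobin) by 3.63 and Ctxn3 by 3.35. With normexp the values were 1.72 for Otop1, 1.83 for Ctxn3 and 2.01 for Cyp2b10. Otop1 was well above background on 2 of 3 WT arrays. WT 1 stood apart for Otop1 (-7.52 against -4.76 and -4.86 in the other WT arrays) and Hp (-2.12 against -0.11 and -0.54), as it did for the adipose genes. Without WT 1 the log2 changes were 3.36 for Otop1 and 3.03 for Hp. Elobl, Cyp2b10, Cyp2b9 and Ctxn3 were lower on Pck1-CKO 3 than on the other 2 arrays of that label. For Cyp2b10 the values were -0.82, -0.63 and -3.20. Without Pck1-CKO 3 the log2 changes were 5.94 for Cyp2b10 and 3.96 for Ctxn3, and the bounds were 43.7-fold for Elobl and 13.1-fold for Cyp2b9.

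The largest decreases also included Krt25 and Chia1, neither well above background on any Pck1-CKO array. They were at least 3.57-fold and 3.59-fold higher in WT, respectively (limma adjusted p = 0.023 and 0.0159). R3hdml fell by 2.43, Zdhhc19 by 2.25, Kynu by 1.95 and Crabp1 by 1.90 on the log2 scale. R3hdml was well above background on 1 of 3 Pck1-CKO arrays. Kynu encodes kynureninase, an enzyme of tryptophan breakdown. Creb3l3, a transcription factor gene of fasting metabolism, fell by 1.77, and Prlr, the prolactin receptor, by 1.59. Most of these were dim, and with normexp the fitted log2 changes were -0.49 for Krt25, -0.46 for Chia1, -0.72 for R3hdml, -1.02 for Zdhhc19, -1.36 for Kynu and -1.25 for Crabp1.

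Of 44 gene lists, 43 had enough tested members for a list test. At an adjusted p under 0.05, 6 lists were higher and 7 lower as a whole by camera with a preset correlation. With an estimated correlation, camera called 0 lists, although 1 higher and 2 lower lists had an unadjusted p under 0.05. Fry, which asks only whether a list's own genes move one way on balance, called 6 higher and 4 lower. For 6 of the 13 lists the per-array median signals of the groups overlapped. These were the mitochondrial ribosome, podocyte, distal tubule, extracellular matrix, complement and endoplasmic reticulum stress lists. This median is taken over genes of different brightness, so it need not follow the genes' own changes. It was 0.90, 0.93 and 0.99 in WT and 1.30, 1.34 and 1.24 in Pck1-CKO for the endothelium list. Yet the median log2 change of that list was -0.12. An overlap of these medians therefore does not show whether a list's genes shifted. The number of higher lists was 3 without WT 1 and 10 without WT 3. Without WT 1 the mitochondrial ribosome, podocyte, extracellular matrix, immediate early and blood lists no longer passed. Without WT 2 the first 4 of these did not. Without WT 3 the blood list did not. Without Pck1-CKO 1 the podocyte and immediate early lists did not, and without Pck1-CKO 2 the extracellular matrix list did not. Further lists passed on leaving out an array. Without WT 3 these were the TCA cycle, amino acid, NAD, mitochondrial biogenesis, p53 and Cre driver lists. Without Pck1-CKO 3 they were the tubular injury, endothelium and male-biased lists. The fatty acid oxidation list passed without WT 2, Pck1-CKO 1 or Pck1-CKO 2, and the adrenal list without Pck1-CKO 1.

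**Figure D2:**
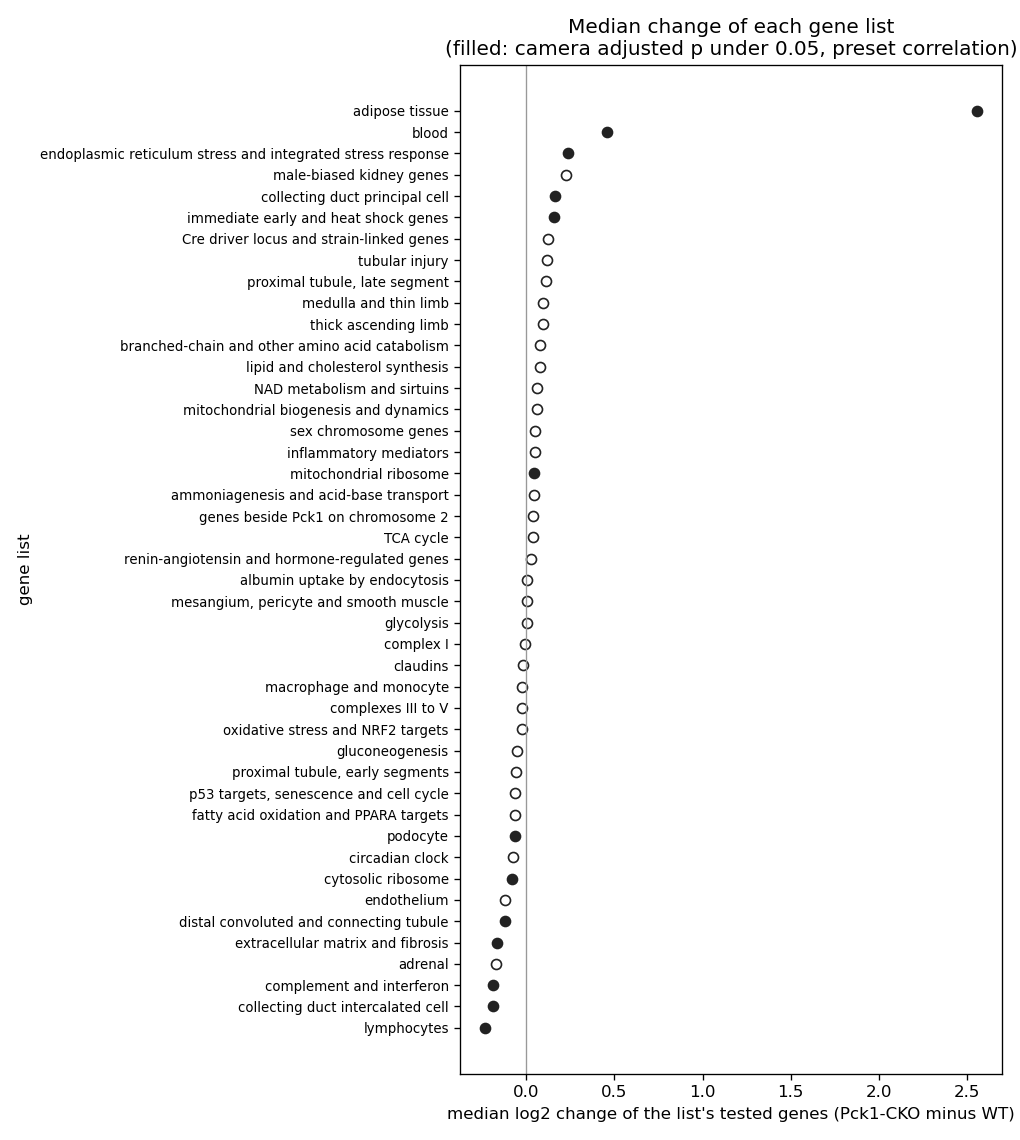
Median log2 change (x axis, Pck1-CKO minus WT) of the tested genes of each of 44 gene lists (y axis). Filled points passed camera at an adjusted p under 0.05 with the preset correlation. The adipose tissue list had the highest median, 2.56, and the lymphocyte list the lowest, -0.23.

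Adipose tissue genes were higher together. Of 14 tested, 5 rose over all genes, with 13 higher and 0 lower adjusted over the list alone, and all 14 had a positive change. Fabp4, the fatty acid binding protein of fat cells, rose by 1.25 ± 0.18 (adjusted p = 0.028), and Car3, a carbonic anhydrase gene abundant in fat, by 2.28 ± 0.40 (adjusted p = 0.0353). The others that passed included Ucp1 and Cidea. For this list the median log2 change was 2.56, with camera adjusted p = 4.80e-06 and adjusted p = 0.492 with an estimated correlation. The level also differed among WT arrays. The list's median log2 signal was -1.75 in WT 1, 0.78 in WT 2 and 0.70 in WT 3, against 3.63, 3.54 and 3.64 in Pck1-CKO.

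In the list of endoplasmic reticulum stress and the integrated stress response, 8 of 21 tested genes were higher, with 10 higher and 1 lower adjusted over the list alone, and 7 had a negative change. Sdf2l1 (log2 change 0.81 ± 0.05, adjusted p = 0.0048), Hsp90b1 (0.43 ± 0.04, adjusted p = 0.0152) and Pdia4 (0.35 ± 0.04, adjusted p = 0.0224) encode proteins that assist folding there. For this list the median log2 change was 0.24, with camera adjusted p = 0.00147 and adjusted p = 0.492 with an estimated correlation. Its per-array median signal was 1.84, 1.81 and 2.06 in WT and 1.88, 1.85 and 1.79 in Pck1-CKO. By this median WT 3 lay above every Pck1-CKO array, and Pck1-CKO 3 below every WT array. It need not follow the genes' own changes, of which 14 of 21 were positive. Heat shock and immediate early genes included 4 of 22 that rose, with 7 higher and 0 lower adjusted over the list alone. Dnajb1 rose by 0.34, Klf2 by 0.41 and Hsph1 by 0.28 on the log2 scale. Here the median log2 change was 0.16, with camera adjusted p = 0.0481 and adjusted p = 0.785 with an estimated correlation. The list shift of immediate early and heat shock genes had camera adjusted p = 0.0507 after quantile normalization (0.00509 to 0.137 over the alternatives run with the preset correlation).

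Among collecting duct intercalated cell genes, 6 of 16 fell, with 0 higher and 9 lower adjusted over the list alone. Aqp6, a water channel gene of acid-secreting cells, changed by -0.94 ± 0.04 (adjusted p = 0.00366), the anion exchanger gene Slc4a1 by -0.88 ± 0.06 (adjusted p = 0.00803), and Dmrt2 by -0.60 ± 0.05. For intercalated cells the median log2 change was -0.19, with camera adjusted p = 4.80e-06 and adjusted p = 0.492 with an estimated correlation. Among principal cell genes, 2 of 13 rose, with 6 higher and 0 lower adjusted over the list alone. The vasopressin-regulated water channel gene Aqp2 changed by 0.63 ± 0.07 (adjusted p = 0.0192) and the vasopressin receptor gene Avpr2 by 0.56 ± 0.11 (adjusted p = 0.0398). For principal cells the median log2 change was 0.16, with camera adjusted p = 0.0217 and adjusted p = 0.492 with an estimated correlation. The difference between both lists was not tested.

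In the distal convoluted and connecting tubule list, 3 of 15 genes fell, with 1 higher and 6 lower adjusted over the list alone. The thiazide-sensitive cotransporter gene Slc12a3 fell by 0.43, the sodium-calcium exchanger gene Slc8a1 by 0.66 and the calcium channel gene Trpv5 by 0.32 on the log2 scale. For this segment the median log2 change was -0.12, with camera adjusted p = 0.00277 and adjusted p = 0.492 with an estimated correlation. In the thick ascending limb list, 2 of 14 rose, Ppp1r1a by 0.31 and the claudin gene Cldn16 by 0.31, with 2 higher and 1 lower adjusted over the list alone, and the median log2 change was 0.10, with camera adjusted p = 0.188 and adjusted p = 0.735 with an estimated correlation. Cldn16 was also the 1 of 16 claudin genes that passed, and in that list the median log2 change was -0.017, with camera adjusted p = 0.659 and adjusted p = 0.847 with an estimated correlation. In it 1 higher and 0 lower adjusted over the list alone passed. In the medulla and thin limb list 4 of 18 rose and 1 fell, including the aldose reductase gene Akr1b3 at 0.61 and the urea transporter gene Slc14a1 at -0.37. There the median log2 change was 0.10, with camera adjusted p = 0.188 and adjusted p = 0.785 with an estimated correlation. This list had 5 higher and 1 lower adjusted over the list alone.

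Podocyte genes were lower as a list only by camera with the preset correlation, and the groups' per-array medians overlapped. Of 27 tested, 2 fell, with 0 higher and 2 lower adjusted over the list alone. Synpo, which encodes an actin-binding protein of podocytes, fell by 0.23 on the log2 scale. For podocytes the median log2 change was -0.063, with camera adjusted p = 0.0472 and adjusted p = 0.735 with an estimated correlation. In the early proximal tubule list none of 21 genes passed in limma (2 higher and 3 lower at an unadjusted p under 0.05), and Ass1 had the lowest p with a log2 change of -0.19 and adjusted p = 0.0726. There the median log2 change was -0.06, with camera adjusted p = 0.307 and adjusted p = 0.847 with an estimated correlation. In the late segment 1 of 15 fell, the transporter gene Slc22a19 (log2 change -0.44 ± 0.07, adjusted p = 0.0307), and the median log2 change was 0.11, with camera adjusted p = 0.551 and adjusted p = 0.847 with an estimated correlation. In it 2 higher and 2 lower adjusted over the list alone passed. Among genes of albumin uptake none of 20 passed in limma (2 higher and 3 lower at an unadjusted p under 0.05). Ctsl, a lysosomal protease gene, had a log2 change of -0.50 and adjusted p = 0.0677. The median of this list was 0.0035, its mean -0.028, and camera gave adjusted p = 0.653 toward lower values, with 0 higher and 0 lower adjusted over the list alone.

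Tubular injury genes included 4 of 26 that rose, with 5 higher and 1 lower adjusted over the list alone. Il34 and Cxcl1, both encoding secreted immune signals, rose by 0.95 and 0.72, and Plin4, a lipid droplet gene of fat cells, by 1.88. Plin4 followed the adipose genes, with -1.60 in WT 1 against -0.61 and -0.75 in the other WT arrays, and 0.71, 0.51 and 1.46 in Pck1-CKO. The list itself did not pass: the median log2 change was 0.12, with camera adjusted p = 0.188 and adjusted p = 0.847 with an estimated correlation. Among p53, senescence and cell cycle genes 3 of 26 rose. These were Phlda3 at 0.43, Cdkn2b at 0.35 and Ccng1 at 0.23. In that list the median log2 change was -0.061, with camera adjusted p = 0.659 and adjusted p = 0.847 with an estimated correlation. This list had 4 higher and 1 lower adjusted over the list alone.

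The lymphocyte list and the complement and interferon list were lower. In the lymphocyte list 2 of 19 genes fell, with 0 higher and 2 lower adjusted over the list alone. These were Gzma, a granzyme of cytotoxic cells, at -1.15 ± 0.20 and the B cell receptor gene Cd79b at -0.44 ± 0.08, and the median log2 change was -0.23, with camera adjusted p = 0.00261 and adjusted p = 0.492 with an estimated correlation. In the complement and interferon list 3 of 30 fell and 1 rose, with 2 higher and 10 lower adjusted over the list alone. Ifit1 fell by 0.42 and Zbp1 by 0.48, whereas the complement gene C4b rose by 1.04. There the median log2 change was -0.19, with camera adjusted p = 0.000582 and adjusted p = 0.735 with an estimated correlation. By the list's median signal WT 3 lay at the Pck1-CKO level, with 1.82, 1.86 and 1.34 in WT and 1.36, 1.26 and 1.29 in Pck1-CKO. Ifit1 and Zbp1, like every gene past the threshold, separated the groups. Their WT 3 values were -1.79 and -1.84, against at most -2.03 and -2.08 in Pck1-CKO. No macrophage or monocyte gene of 21 passed in limma (5 higher and 8 lower at an unadjusted p under 0.05), and the median log2 change was -0.023, with camera adjusted p = 0.484 and adjusted p = 0.847 with an estimated correlation. The lowest p in that list was that of Cybb, with a log2 change of -0.29 and adjusted p = 0.0545. Of 22 inflammatory mediator genes, the chemokine gene Ccl3 fell by 0.87, well above background on 1 of 3 Pck1-CKO arrays. With normexp the log2 change of Ccl3 was -0.24, and it did not pass under 9 alternatives. In this list 13 genes had a positive and 9 a negative change (6 higher and 4 lower at an unadjusted p under 0.05), and the median log2 change was 0.05, with camera adjusted p = 0.659 and adjusted p = 0.847 with an estimated correlation. Its log2 changes ranged from -0.87 to 4.60 with a mean of 0.40, and none of its genes that rose passed. The extracellular matrix and fibrosis list was lower as a whole with no member past the threshold in limma (0 higher and 5 lower at an unadjusted p under 0.05, of 29), and the median log2 change was -0.17, with camera adjusted p = 0.0364 and adjusted p = 0.831 with an estimated correlation. Its per-array median signal was 0.05, 0.04 and -0.17 in WT and -0.13, -0.23 and 0.12 in Pck1-CKO. By this median Pck1-CKO 3 lay above every WT array. Its lowest p was that of Mmp2, with a log2 change of -1.01 and adjusted p = 0.0744.

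Blood genes were higher as a list by camera with the preset correlation and by fry, but not with an estimated correlation. Ppbp, a platelet gene, rose by 1.94 ± 0.09 (adjusted p = 0.00366; 1.26 with normexp), and the neutrophil gene S100a8 by 1.70 ± 0.27 (adjusted p = 0.0308). In all 3 of 10 rose and 1 fell, Slc4a1, which intercalated cells also express. Here the median log2 change was 0.46, with camera adjusted p = 0.0366 and adjusted p = 0.492 with an estimated correlation. This list had 7 higher and 1 lower adjusted over the list alone. Endothelial genes went both ways, with 2 of 18 higher and 1 lower. Plat changed by 0.59, Nos3 by 0.26 and Erg by -0.38, and the median log2 change was -0.12, with camera adjusted p = 0.112 and adjusted p = 0.785 with an estimated correlation. In it 2 higher and 2 lower adjusted over the list alone passed. In the list of mesangium, pericyte and smooth muscle, Notch3 and Tagln were the 2 of 16 that rose, by 0.28 and 0.27. Its median was 0.0027, its mean -0.059, and camera gave adjusted p = 0.754 toward lower values, with 3 higher and 3 lower adjusted over the list alone.

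Ribosomal protein genes of both compartments shifted by small amounts. Of 76 cytosolic ribosome genes, 73 had a negative and 3 a positive change, and the median log2 change was -0.081, with camera adjusted p = 1.08e-08 and adjusted p = 0.492 with an estimated correlation. Single members rarely passed. Rps16 fell by 0.17 and Rpl37 rose by 0.44, with 0 higher and 0 lower adjusted over the list alone. The Rpl37 probe was dim (-4.10 on average in WT). With normexp its log2 change was 0.06 and adjusted p = 0.617 (0.028 to 0.617 over the alternatives), and it did not pass under 11 alternatives. Rps16, with adjusted p = 0.0499, did not pass under 13, the deposited matrix among them. Of 80 mitochondrial ribosome genes 61 had a positive change, 2 rose and 1 fell. These were Mrpl35 at 0.48, Mrpl36 at 0.23 and Mrpl23 at -0.22. Here the median log2 change was 0.046, with camera adjusted p = 0.0217 and adjusted p = 0.847 with an estimated correlation. In it 2 higher and 1 lower adjusted over the list alone passed. After quantile normalization the list shift of mitochondrial ribosome genes had camera adjusted p = 0.448 (2.27e-05 to 0.448 over the alternatives run with the preset correlation). The list was included because a paper of this group on Pck1 knockout kidneys discusses mitochondrial ribosomes. It may therefore have been chosen on these samples and is not independent evidence.

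None of the 6 metabolic lists below passed camera as fixed beforehand. Among gluconeogenesis genes Pck2, the mitochondrial counterpart of Pck1, fell by 0.20 and Creb3l3 by 1.77, 2 of 15 tested, and the median log2 change was -0.054, with camera adjusted p = 0.186 and adjusted p = 0.735 with an estimated correlation. This list had 0 higher and 2 lower adjusted over the list alone. The hexokinase gene Hk2 was the 1 of 20 glycolysis genes to pass (log2 change 1.84 ± 0.17, adjusted p = 0.0149), and the median log2 change was 0.0024, with camera adjusted p = 0.659 and adjusted p = 0.847 with an estimated correlation. In it 1 higher and 0 lower adjusted over the list alone passed. With normexp the log2 change of Hk2, a dim gene, was 0.66. In the list of fatty acid oxidation and PPARA targets Cyp4a12a rose by 1.90 ± 0.11 (adjusted p = 0.00425) and 3 of 30 fell, among them the thiolase gene Acaa2 (-0.35). There the median log2 change was -0.061, with camera adjusted p = 0.0538 and adjusted p = 0.847 with an estimated correlation. This list had 1 higher and 4 lower adjusted over the list alone. The list shift of fatty acid oxidation and PPARA targets was past the threshold toward lower values under 6 alternatives. These were quantile normalization (adjusted p = 0.0201), the intensity trend, the stricter filter, and leaving out WT 2, Pck1-CKO 1 or Pck1-CKO 2. Its camera adjusted p ranged from 0.00533 to 0.719 over the alternatives run with the preset correlation. Among amino acid genes the serine synthesis genes Psat1 and Phgdh moved apart, 0.86 ± 0.08 against -0.74 ± 0.08, and Kynu fell, 3 of 36 in all. There the median log2 change was 0.078, with camera adjusted p = 0.146 and adjusted p = 0.847 with an estimated correlation. In it 3 higher and 2 lower adjusted over the list alone passed. Among ammoniagenesis and acid-base genes 1 of 16 rose and 3 fell, namely Slc4a1, the ammonium transporter gene Rhbg (-0.40) and the glucose transporter gene Slc2a2 (-0.42). Camera gave adjusted p = 0.623 toward lower values, although the median was 0.046 and the mean 0.0015, with 3 higher and 4 lower adjusted over the list alone. Nnmt was the 1 of 21 genes of NAD metabolism to pass, at 0.95, and the median log2 change was 0.064, with camera adjusted p = 0.138 and adjusted p = 0.847 with an estimated correlation. In it 1 higher and 0 lower adjusted over the list alone passed.

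No gene passed in limma in 6 further metabolic and stress lists. The TCA cycle list had 20 tested genes (4 higher and 0 lower at an unadjusted p under 0.05), and the median log2 change was 0.037, with camera adjusted p = 0.129 and adjusted p = 0.847 with an estimated correlation. Its lowest p was that of Idh3a (log2 change 0.29, adjusted p = 0.0574). Complex I had 37 (0 higher and 0 lower at an unadjusted p under 0.05), and the median log2 change was -0.0062, with camera adjusted p = 0.551 and adjusted p = 0.865 with an estimated correlation. Complexes III to V had 34 (0 higher and 2 lower at an unadjusted p under 0.05), and the median log2 change was -0.024, with camera adjusted p = 0.188 and adjusted p = 0.847 with an estimated correlation. Lipid and cholesterol synthesis had 24 (5 higher and 3 lower at an unadjusted p under 0.05), and the median log2 change was 0.076, with camera adjusted p = 0.484 and adjusted p = 0.847 with an estimated correlation. Mitochondrial biogenesis and dynamics had 24 (5 higher and 0 lower at an unadjusted p under 0.05), and the median log2 change was 0.063, with camera adjusted p = 0.082 and adjusted p = 0.785 with an estimated correlation. Oxidative stress and NRF2 targets had 25 (3 higher and 5 lower at an unadjusted p under 0.05), and the median log2 change was -0.026, with camera adjusted p = 0.487 and adjusted p = 0.847 with an estimated correlation.

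Hormone-related and sex-biased genes changed in both directions. In the renin-angiotensin and hormone-regulated list 3 of 23 fell and 1 rose. Angiotensinogen (Agt) changed by -0.57 ± 0.06 and the vitamin D-degrading enzyme gene Cyp24a1 by -1.12 ± 0.23, whereas the glucocorticoid-responsive gene Tsc22d3 changed by 0.61 ± 0.10. Camera gave adjusted p = 0.654, toward lower values although the median was 0.029 and the mean was -0.042, with 3 higher and 6 lower adjusted over the list alone. Of 14 genes with a known sex bias in kidney 5 rose and 3 fell, with 7 higher and 3 lower adjusted over the list alone. Cyp4a12b rose by 1.88 ± 0.11 and Cyp2j13 by 0.58 ± 0.07, while Slc7a12 fell. Slc7a12 is known to be higher in female kidney, so its fall does not oppose the rise of Cyp4a12b and Cyp2j13, listed as male-biased. Prlr, named above and also in this list, had a log2 change of -1.59. Cyp4a12a and Cyp4a12b are near-identical relatives, so their values are not independent. For the list the median log2 change was 0.23, with camera adjusted p = 0.112 and adjusted p = 0.735 with an estimated correlation. By fry it was higher, with adjusted p = 0.0256.

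The remaining lists describe the samples. Of 4 tested sex chromosome genes none passed in limma (1 higher and 1 lower at an unadjusted p under 0.05), and Ddx3y, on the Y chromosome, was well above background on all 6 arrays (log2 change 0.24, adjusted p = 0.128). No circadian gene of 17 passed in limma (1 higher and 6 lower at an unadjusted p under 0.05), and the median log2 change was -0.076, with camera adjusted p = 0.164 and adjusted p = 0.785 with an estimated correlation. Cry2 had the lowest p there, with a log2 change of -0.57 and adjusted p = 0.0868. No adrenal gene of 8 passed in limma (0 higher and 2 lower at an unadjusted p under 0.05), and the median log2 change was -0.17, with camera adjusted p = 0.146 and adjusted p = 0.735 with an estimated correlation. Akr1b7 had the lowest p of these, with a log2 change of -0.19 and adjusted p = 0.0834. Among genes beside Pck1 on its chromosome 4 of 22 rose and 1 fell. Those higher included Rbm38 at 0.71, Stx16 at 0.24 and Rab22a at 0.19. The 1 lower was Zbp1 at -0.48, which is also in the complement and interferon list. For the genes beside Pck1 the median log2 change was 0.038, with camera adjusted p = 0.487 and adjusted p = 0.785 with an estimated correlation. This list had 6 higher and 2 lower adjusted over the list alone. Among genes of the Cre driver locus and strain-linked genes none of 11 passed in limma (5 higher and 0 lower at an unadjusted p under 0.05), and the median log2 change was 0.12, with camera adjusted p = 0.112 and adjusted p = 0.785 with an estimated correlation. The lowest p there was that of Adora2a, with a log2 change of 0.37 and adjusted p = 0.0605. Adjusted over the list alone, no gene passed in limma in the lists of proximal tubule early segments, macrophage and monocyte, inflammatory mediators, extracellular matrix and fibrosis, TCA cycle, complex I, complexes III to V, lipid and cholesterol synthesis, mitochondrial biogenesis and dynamics, oxidative stress and NRF2 targets, circadian clock, adrenal and Cre driver locus and strain-linked genes.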

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

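The weighing of 2 patterns below used tests chosen after the results were seen, except for the change of the further adipose genes, which was set before its values were seen.

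Probes without a gene symbol, which no comparison of the genes used, also differed from WT. Tested probe by probe, 589 of 12849 passed the adjusted threshold, 131 higher and 458 lower in the arrays labelled Pck1-CKO. Probe A_30_P01026259, chosen after its values were seen, was well above background on all 3 WT arrays and on 0 of 3 Pck1-CKO arrays (limma adjusted p = 0.00746). The same held for A_30_P01032673 (limma adjusted p = 0.0258). Both probes are named for the same genomic region, so they are not separate findings.

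Adipose transcripts were higher in the arrays labelled Pck1-CKO. Perirenal fat carried with the kidney may account for this. A median log2 change over 1 in 22 further adipose genes was set to speak for it and one under 0.2 against it, and the median of the 20 tested was 0.17. That met the bound against it, but by less than the members' spread of 0.59, a criterion applied only after the value was seen, and genes such as Gpd1 and Cox7a1 were already bright in WT kidney, which would hide a small share of fat. The 7 dim in WT, chosen after seeing the values, had a median of 2.51, but this decides nothing, since 5 of them passed the filter only through the Pck1-CKO arrays, and Lhx8, nearly as dim, changed by -0.14. Genotype as the whole cause needs level WT arrays, yet the 9 adipose genes that changed by over 1 were lower in WT 1 by a median of 2.60, while the other WT arrays differed by 0.27. That gap rests on 1 array and excludes nothing, so fat carried along and a genotype effect on adipose genes cannot be told apart.

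Pck1 was not lower in the arrays labelled Pck1-CKO. Exchanged labels could give this, and with adjusted p = 0.152 for Pck1 the test decides neither way. A probe outside the deleted part could give it too, and with 1 probe on the array this cannot be told apart from the others. Pck1 RNA from carried fat might add to the signal, but WT 1, with the least adipose signal, had a Pck1 value 0.32 above the mean of the other WT arrays, and 1 array excludes nothing. In Pck1-CKO 1 to 3, Pck1 was at 6.44, 6.60 and 6.90, while the adipose list medians were nearly level at 3.63, 3.54 and 3.64. Such a small difference over 3 arrays decides nothing. A loss confined to part of the tubule was not tested.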

How the results depend on the processing

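Of the alternatives, 2 were chosen after seeing the data, leaving out WT 3 with Pck1-CKO 3 and leaving out genes lower in WT 1. Pck1 stayed above WT and short of the threshold under every alternative run, from 0.21 to 0.68 on the log2 scale. Quantile normalization, normexp, the deposited matrix, kept flags, the mean of a gene's probes, a stricter filter and leaving out genes lower in WT 1 kept the counts of genes higher in Pck1-CKO and genes lower in Pck1-CKO within 1.5 times of 743 and 634. Of the 1377 genes, 3 changed sign with normexp and 8 with the mean of a gene's probes, none of them named. Without a filter 61 genes were higher and 81 lower among 23781 tested. An intensity trend with robust variance gave 1682 and 1149, and array weights 3286 and 2614. Leaving out WT 3 and Pck1-CKO 3, whose Dbp values stood apart, gave 1304 and 1154. Testing each probe gave 984 lower. Without 1 array in turn the counts ranged from 16 to 779 higher and from 9 to 806 lower, and 0 of the 1377 genes changed sign. The number of higher lists was 10 without a filter, 10 with array weights, 11 without WT 3 and Pck1-CKO 3, and ranged from 3 to 10 without 1 array. It was 0 for higher and 0 for lower lists with an estimated correlation in camera, which allows for genes that vary together, and fry called 4 lower. The lower lists ranged from 5 to 8 without 1 array. With the replicate number as a block 3 genes were higher and 1 lower. Whether the numbers pair the samples cannot be told. Deviations of same-numbered samples correlated at -0.001, -0.11 and -0.02, but 3 arrays per group cannot show that samples are unpaired. The number was also the slide column in both groups. Principal component 2 of the arrays (14.3% of variance) was -14.7, 1.07 and 11.6 in WT 1 to 3. In Pck1-CKO 1 to 3 it was -11.4, -4.29 and 17.7. Among named genes past the threshold 2 of 85 kept their side under every alternative and none reversed, and among lists 8 of 13 did in camera with the preset correlation. Of 30 lists short of the threshold 12 passed in camera with the preset correlation under at least 1 alternative. By fry the list named male-biased and the genes beside Pck1 were higher, each with adjusted p = 0.0256. The former also holds Slc7a12, known to be higher in female kidney, whose fall counts toward lower values in that list. The list's shift therefore does not measure one toward male values. Fold changes of named genes moved by over 1.5 times in 16 of 85 with normexp, all toward smaller sizes, in 5 without WT 1, in 4 without Pck1-CKO 3, in 1 without WT 3, in 2 with array weights, in 2 without both WT 3 and Pck1-CKO 3, and in 1 with the mean of a gene's probes. Except where fewer arrays, more genes tested or the correlation itself shows it, the cause was not tested. Genes near background are limited by signal.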

Other observations

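The tests in this part on gene neighbours were chosen after the pattern was seen, and the comparison with other splits was set beforehand.

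The long noncoding RNA gene 2610035D17Rik, chosen after its values were seen, had a log2 change of -5.18 ± 0.28 (limma adjusted p = 4.25e-03), with -0.85, -0.91 and -0.71 in WT and -6.62, -5.51 and -5.88 in the arrays labelled Pck1-CKO. Zfp874a, likewise chosen afterwards, was at -0.02, -0.07 and 0.01 in WT, at -8.03 and -8.06 in Pck1-CKO 1 and 2, and at -0.83 in Pck1-CKO 3. The clock output gene Dbp was higher in WT 3 by 0.79 than in the other WT arrays and in Pck1-CKO 3 by 0.83 than in the others of that label. Cytosolic ribosome genes had a median log2 change of -0.081 against 0.0053 for 337 other genes of the same brightness.

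Of the 10 splits of the 6 arrays into groups of 3, only 1, the real one, gave 1377 genes, and the highest other gave 0 in limma (at most 1132 at an unadjusted p under 0.05, against 5354). With 10 splits no share under 0.05 can be reached. Every other split mixes the labels, so any group difference adds to its spread, and its count does not show what chance gives.

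In a window of 20 neighbouring tested genes around Rsl1, 6 were past the threshold with an absolute log2 change over 0.4. Those higher included Zfp458 (1.83), Zfp459 (0.84) and Zfp748 (0.79), and Zfp493 was lower (-0.52). The window also held Zfp874a, described above (log2 change -5.61, limma adjusted p = 0.127). It did not pass, so neither this count nor the shuffles below include it as a called gene. Chance placement may account for the cluster, since 26.2% of 1000 shuffles of the gene order gave a window as full. Probes shared between related zinc finger genes may also contribute, and with 0 called genes of another kind, and 1 such gene in the window, this cannot be told apart.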
